A study of Streptomyces coelicolor with 23 samples.

How the data were processed

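RNA was measured by sequencing in Streptomyces coelicolor M145 grown in liquid ISP2 medium and sampled daily for 8 days. The labels describe RNA extraction with phenol and chloroform and a column with DNase treatment, removal of ribosomal RNA, and single-end sequencing on a HiSeq instrument. They give 3 biological replicates per day. The labels list no day 8 replicate 1, so there were 23 libraries, grouped by the day and replicate in their titles.

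The deposited table holds 2 scores per gene and library, a normalised expression score and an RPKM score, both made by the authors and both rounded to whole numbers. The labels call the output log2 transformed, but the deposited expression scores run on a linear scale and were treated as linear. Within a library the expression score was a constant multiple of the RPKM, and the upper quartile was nearly the same in all libraries, so the authors' values were scaled between libraries and by gene length before they were deposited. The aligner, the counting program and the genome build are not given. No read totals are given either, so the depth per library is unknown, and no counting error, detection limit or count model could be used. Because the values are whole numbers, a value of 0 stands for anything that rounds to 0.

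Of 48 columns of values per library, 46 belonged to the 23 libraries and 2 belonged to a day 8 replicate 1 that the labels do not list, which was left out with the columns of averages and coefficients of variation. Expression scores were used for all comparisons, and RPKM served to check the column headers. That check found the headers of day 5 replicate 2 and day 6 replicate 2 exchanged between both sets of columns. The headers of the expression columns were followed, and the closing section gives the effect.

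Genes at the lowest value of a library in more than a share of 0.5 of the libraries were dropped, which left 7831 of 7853 genes. Values were analysed as log2(value + 1) with limma 3.58.1 in R 4.3.3, with 1 mean per day over all 23 libraries and an empirical Bayes step with a mean-variance trend. The plan had been to use log2 values as deposited, and the pseudocount of 1 was its alternative for linear values. A moderated F test covered all days, and 13 two-sided contrasts compared each day with day 1 and each day with the day before. P-values were adjusted by Benjamini-Hochberg within each test at a threshold of 0.05. Replicate numbers were not used as blocks, since the labels do not say what a number shares between days, and the fit with the block is among the alternatives.

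In all, 42 gene lists with 487 members were set by SCO number: biosynthetic clusters, primary functions, and development and stress. The level of a list in a library is the mean of log2(value + 1) over its members. Lists were tested by camera in limma with a preset correlation of 0.01 between genes, adjusted over lists and contrasts within each family, against day 1 or between consecutive days. The test was repeated with an estimated correlation and with fry. Random regroupings of the libraries gave up to 232 calls with the preset correlation, against 238 for the real days. Such regroupings mix libraries of different days, so they do not measure false calls between the real days. With an estimated correlation camera called 0 tests, so the preset p-values alone are not taken as support for any list. Member calls were counted over all genes and adjusted over the list alone.

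Named genes were chosen by rule. For days 3, 5 and 8 against day 1 these were the 8 largest rises and 8 largest falls among called genes whose libraries of both days did not overlap, and for consecutive days the 3 largest rises and falls. For the test over all days they were the 5 genes with the widest range of day means in each of 3 classes of peak day. From each list the rule took members with a gene name and the 2 members with the largest change. Named members enter the counts, and values are printed for only some of them. Genes carry the identifiers and products of the table, and what a list or gene is known for is background knowledge. The lists, the tests, the naming rule and the first set of alternatives were chosen before the data were examined.

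The workflow was tested on simulated data with 7831 genes. In the contrast of days 3 and 1 it recovered 79.7% of changes of 1 on the log2 scale, 98.6% of changes of 2 and 100% of changes of 4, with 13 false calls. Between days 3 and 2 it recovered 72.9% of changes of 1, with 8 false calls, and in a contrast with no change it made 0 false calls. Only 59, 70 and 71 genes were given changes of 1, 2 and 4, drawn from genes with a mean log2 value above 3. When the ATP synthase list was shifted on day 3, camera with the preset correlation found 3 of 3 shifted comparisons. It called 0 of 543 others. Genes were simulated as varying independently, with no shift of whole libraries, so lists whose members vary together were not covered. The real days differed in far more genes, many of them low, so these figures need not hold for the real data.

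Alternatives tried were median-centring, quantile normalisation, no filter, dropping a further 25% of genes with the lowest means, no trend, a robust fit, library weights from arrayWeights, the replicate number as a block or as a random effect (statmod 1.5.0), an added 2-fold threshold, pseudocounts of 0.1 and 10, fits on only both days compared, and leaving out each library in turn. Added after the data were seen were subtraction of the 5th percentile of each library as background, scaling to equal sums over protein-coding genes, and exchanging or leaving out day 5 replicate 2 and day 6 replicate 2.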

Results

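RNA from Streptomyces coelicolor M145, a soil bacterium that makes several antibiotics, was sequenced from liquid ISP2 cultures sampled once a day for 8 days. The series holds 23 libraries, with 3 biological replicates on each of days 1 to 7 and 2 on day 8. One table gives a normalised expression value per library for 7853 genes, and 7831 of them entered the tests. Values below are means ± SD of these normalised expression values with n = 3 libraries per day and n = 2 on day 8. The level of a gene list is the mean of log2(value + 1) over its members. A log2 change is on that same scale, which understates the change of low genes. The table gives no read totals, so the depth of the libraries is unknown and no detection limit can be given. Where the largest rises or falls are named, they are those among called genes whose libraries of the 2 days did not overlap. Replicates of one day correlated across genes with r between 0.970 and 0.994, a description over genes that are not independent replicates.

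The distribution of values changed after day 1. The number of genes listed at 0 was 918 ± 24.2 per library on day 1, 99.3 ± 36.6 on day 2 and 28 ± 15.1 on day 6. The lower quartile of the values was 4 on day 1 and 14 ± 1.73 on day 6, and the median was 25.3 ± 1.15 and 38.7 ± 1.15, while the upper quartile lay between 115 and 118 in the day 1 libraries and between 110 and 113 in those of day 6. Ribosomal RNA genes held 0.623 ± 0.283% of the summed values on day 1, 14.0 ± 1.16% on day 4, 34.4 ± 2.97% on day 6 and 25.2 ± 6.95% on day 8. Ribosomal RNA was removed before sequencing, so these shares depend on how much of it was left. SCOs02, a stable RNA that the table leaves without a product, held 8.48% to 9.38% on day 1 and 34.4 ± 0.969% on day 5. The median log2 change over all genes against day 1 was between 0.27 on day 2 and 0.66 on day 6, so a change of one gene is best read against that shift. Between consecutive days it was -0.11 from day 2 to day 3, 0.15 from day 5 to day 6 and -0.14 from day 6 to day 7.

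**Figure D1:**
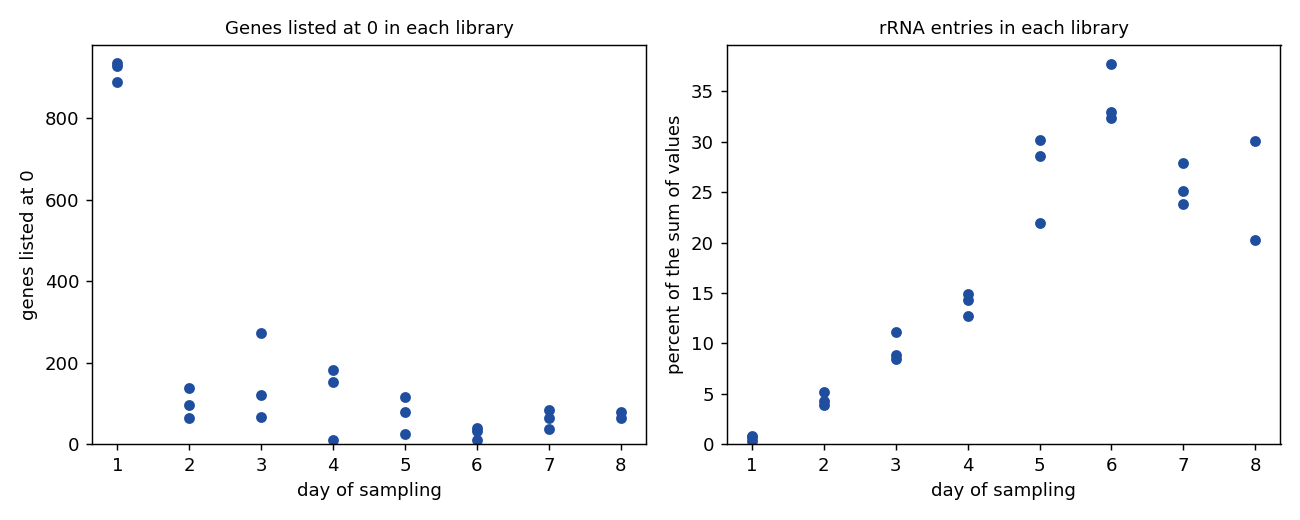
Genes listed at 0 per library (left, number of genes) and the percentage of the summed normalised expression values held by ribosomal RNA genes (right), by day of sampling. Each point is 1 library, and the day 1 libraries have 890 to 935 genes listed at 0.

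Nearly the whole transcriptome moved over the 8 days. The levels of the actinorhodin, coelimycin, undecylprodigiosin and calcium-dependent antibiotic lists were highest on day 2 or day 3. Among all called genes, day 1 was the most common day of the highest mean. The limma F test over all days called 7139 of 7831 genes at an adjusted p below 0.05. The day with the highest mean was day 1 for 2022 of these genes, day 2 for 767, day 3 for 676, day 4 for 377, day 5 for 216, day 6 for 1871, day 7 for 566 and day 8 for 644. These peaks come from values that were not rescaled, and the median value was 38.7 ± 1.15 on day 6 against 25.3 ± 1.15 on day 1. The day 6 count therefore cannot be told apart from that general lift of low values. The 5 widest ranges among genes highest on days 2 to 4 all belonged to the actinorhodin cluster (SCO5087, SCO5073, SCO5072, SCO5086 and SCO5088). SCO5087, the alpha subunit of the actinorhodin beta-ketoacyl synthase, had means of 0.667 ± 0.577 on day 1, 8385 ± 1921 on day 3 and 708 ± 141 on day 8. Among genes highest on days 5 to 8, the widest ranges were those of SCO4677, a regulatory protein, SCO1330, a fatty acid CoA ligase, SCO1329, SCO2804 and the glycosyl hydrolase SCO6572. SCO4677 was listed at 0 in all day 1 libraries and reached 2927 ± 253 on day 5. SCO1330 went from 1 ± 0 on day 1 to 2750 ± 752 on day 7. SCO5656, a transcriptional regulator, SCO1454, an amino oxidase, SCO5655, the transketolase SCO6663 and the dehydrogenase SCO4945 had the widest ranges among genes highest on day 1.

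Day 2 was set against day 1, the first sampling, to show what had moved after 1 further day. Several clusters for antibiotics and other specialised metabolites were far higher on day 2, but not all. For actinorhodin, a blue polyketide antibiotic, 21 of 22 members rose and 1 did not pass, with the same numbers adjusted over the list alone, at 2.78 ± 0.32 and 10.07 ± 0.45 (camera adjusted p = 7.2e-17, adjusted p = 0.264 with an estimated correlation). In the coelimycin cluster, which makes a polyketide antibiotic, 19 of 20 members rose and 1 did not pass, with the same numbers adjusted over the list alone, and the list level went from 2.88 ± 0.12 to 9.59 ± 0.45 (camera adjusted p = 8.9e-14, adjusted p = 0.239 with an estimated correlation). The largest rises of all genes were in this cluster: the 3-oxoacyl-ACP reductase SCO6282 went from 18.3 ± 9.71 to 39856 ± 11460.2, the epoxide hydrolase SCO6277 from 1 ± 0 to 3999 ± 1708 and SCO6276 from 1.33 ± 0.577 to 4062 ± 1798. For the calcium-dependent antibiotic, a lipopeptide, 36 of 40 members rose, 1 fell and 3 did not pass, with the same numbers adjusted over the list alone, at list levels of 1.56 ± 0.05 and 7.75 ± 0.71 (camera adjusted p = 1.7e-16, adjusted p = 0.384 with an estimated correlation). The CDA peptide synthetase I (SCO3230) was listed at 0 in all day 1 libraries and at 151 ± 73.9 on day 2. For the non-ribosomal peptide cluster around SCO6429, all 10 members rose, with the same numbers adjusted over the list alone, at 0.95 ± 0.27 and 7.33 ± 0.65 (camera adjusted p = 2.2e-06, adjusted p = 0.39 with an estimated correlation). The deoxysugar cluster, a group of sugar-modifying enzymes, had 21 of 21 members higher (the same numbers adjusted over the list alone), at 1.77 ± 0.17 and 8.24 ± 0.41 (camera adjusted p = 2.2e-18, adjusted p = 0.264 with an estimated correlation).

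In 3 other clusters most members were not called higher on day 2. For undecylprodigiosin, a red tripyrrole antibiotic, 6 of 22 members rose, 2 fell and 14 did not pass, with the same numbers adjusted over the list alone. Its level was 3.91 ± 0.14 on day 1 and 4.08 ± 0.41 on day 2, and the direction of the camera test (camera adjusted p = 0.85) differed in sign from the mean change of 0.17 and the median of 0.15. That mean change was 0.11 without day 1 replicate 3, 0.35 without day 2 replicate 2 and -0.0505 without day 2 replicate 3, and it was also negative after median-centring, quantile normalisation or background subtraction. For isorenieratene, a carotenoid, 2 of 7 members fell and 5 did not pass, with the same numbers adjusted over the list alone, at 3.84 ± 0.21 and 3.23 ± 0.15 (camera adjusted p = 0.164). For ectoine, a compatible solute, 3 of 4 members fell and 1 did not pass, with the same numbers adjusted over the list alone, at 8.39 ± 0.08 and 7.34 ± 0.14 (camera adjusted p = 0.0498, adjusted p = 0.434 with an estimated correlation). The camera adjusted p of ectoine was between 0.0511 and 0.0651 without day 1 replicate 2 or 3, day 2 replicate 1 or 3, day 4 replicate 2 or 3, day 6 replicate 2 or day 7 replicate 1.

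Respiration genes went both ways between days 1 and 2. For ATP synthase, all 8 members fell, with the same numbers adjusted over the list alone, at 11.84 ± 0.10 and 9.77 ± 0.66 (camera adjusted p = 1.1e-04, adjusted p = 0.39 with an estimated correlation). For the cytochrome bc1-aa3 branch, all 6 members fell, with the same numbers adjusted over the list alone, at 12.13 ± 0.01 and 10.65 ± 0.52 (camera adjusted p = 0.00267, adjusted p = 0.434 with an estimated correlation). For the NADH dehydrogenase genes (nuo), 12 of 14 members rose and 2 did not pass, with the same numbers adjusted over the list alone, at 4.20 ± 0.09 and 5.81 ± 0.39 (camera adjusted p = 4.2e-04, adjusted p = 0.485 with an estimated correlation). In the list of cytochrome bd oxidase and nitrate reductases, 9 of 14 members rose, 1 fell and 4 did not pass, with the same numbers adjusted over the list alone (camera adjusted p = 0.00208, adjusted p = 0.39 with an estimated correlation). The nitrate reductase subunit delta NarJ3 (SCO4949) rose from 2.33 ± 0.577 to 2549 ± 1088.

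Genes for maltose uptake, arginine biosynthesis and the hyphal surface were higher on day 2. For maltose uptake, all 5 members rose, with the same numbers adjusted over the list alone, and the level was 6.18 ± 0.07 on day 1 and 9.55 ± 0.51 on day 2 (camera adjusted p = 6.1e-04, adjusted p = 0.363 with an estimated correlation). The maltose permease SCO2230 rose from 50 ± 7 to 974 ± 352. In the arginine biosynthesis list, all 7 members rose, with the same numbers adjusted over the list alone, at 5.22 ± 0.13 and 7.97 ± 0.38 (camera adjusted p = 0.00324, adjusted p = 0.449 with an estimated correlation). Of the chaplins and rodlins, small proteins that coat aerial hyphae, 10 of 10 rose (the same numbers adjusted over the list alone), at 2.36 ± 0.03 and 6.33 ± 0.25 (camera adjusted p = 1.8e-05, adjusted p = 0.146 with an estimated correlation). SCO1800, a member of that list, went from 23.7 ± 8.08 to 7315 ± 985. The largest falls were those of the amino oxidase SCO1454, from 382 ± 26 to 2 ± 1, the L-threonine 3-dehydrogenase SCO6799, from 362 ± 33.1 to 6 ± 2.65, and its neighbour in number, the 2-amino-3-ketobutyrate coenzyme A ligase SCO6800, from 334 ± 67.4 to 5.33 ± 1.53. The limma contrast called 5345 genes, 3173 higher and 2172 lower. The share of higher genes among the calls was 59.4%, against 39.4% after quantile normalisation and 47.9% after background subtraction.

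Nitrogen assimilation genes under GlnR were spread widely on day 2. Over the 19 members, the list level was 7.00 in day 2 replicate 1, 9.59 in replicate 2 and 6.58 in replicate 3, against 5.88 ± 0.09 on day 1. 14 members rose and 5 did not pass (16 higher adjusted over the list alone; camera adjusted p = 0.0142, adjusted p = 0.536 with an estimated correlation). The mean change of 1.85 was 0.92 without day 2 replicate 2, where the camera adjusted p was 0.0913. By day 3 the level was 9.01 ± 0.50, 16 members were higher than on day 1 and 0 lower (the same numbers adjusted over the list alone; camera adjusted p = 0.0144, adjusted p = 0.536 with an estimated correlation). The nitrite reductase large subunit NirB (SCO2487) went from 0.333 ± 0.577 on day 1 to 1694 ± 1086 on day 3, the ammonium transporter SCO5583 from 128 ± 28.4 to 2179 ± 967, and the glutamine synthetase SCO2210 from 294 ± 14.2 to 3319 ± 1647.

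**Figure D2:**
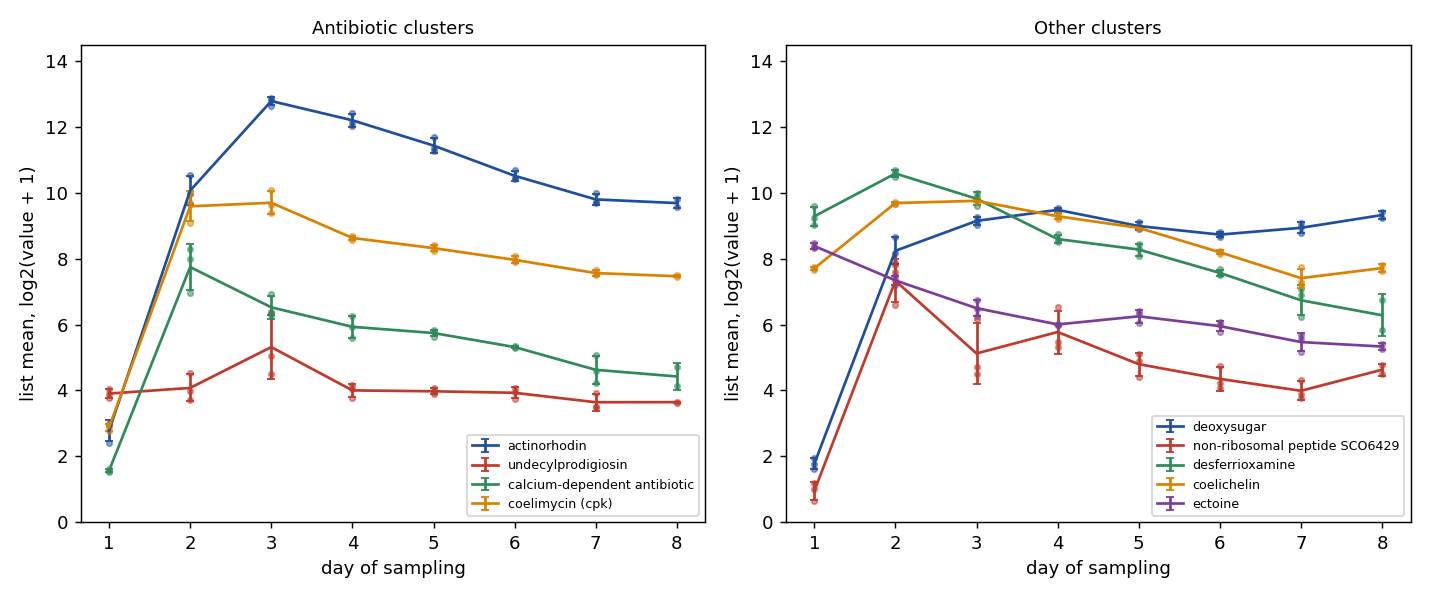
Level of 9 biosynthetic gene lists by day, as the mean of log2(normalised expression + 1) over the members. Points are libraries, lines join day means and bars are SD. Actinorhodin reaches 12.79 ± 0.12 on day 3, while the calcium-dependent antibiotic list is highest on day 2 at 7.75 ± 0.71.

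Day 3 against day 1 shows the culture at the peak of the actinorhodin genes. In this cluster, all 22 members rose, with the same numbers adjusted over the list alone, and the level went from 2.78 ± 0.32 to 12.79 ± 0.12 (camera adjusted p = 4.1e-17, adjusted p = 0.264 with an estimated correlation). All 8 of the largest rises were in this cluster (SCO5087, SCO5073, SCO5072, SCO5086, SCO5088, SCO5071, SCO5089 and SCO5074), with log2 changes between 11.64 and 12.34 and adjusted p between 5.9e-22 and 2.5e-17. The actinorhodin cluster activator protein (SCO5085) rose from 33.7 ± 0.577 to 10524 ± 1685. For undecylprodigiosin, 15 of 22 members rose, 1 fell and 6 did not pass, with 16 higher and 1 lower adjusted over the list alone, at 3.91 ± 0.14 and 5.32 ± 0.97 (camera adjusted p = 0.0294, adjusted p = 0.636 with an estimated correlation). Its regulator RedD (SCO5877) rose from 16 ± 1 to 240.3 ± 128. The undecylprodigiosin change of 1.41 was 0.87 without day 3 replicate 3 (camera adjusted p = 0.155). The camera adjusted p was 0.0517 without day 1 replicate 3. Both gamma-butyrolactone genes, ScbA (SCO6266) and the gamma-butyrolactone binding protein (SCO6265), rose from 6 ± 1 to 85 ± 16.7 and from 94 ± 12.5 to 314 ± 25.6, with the same numbers adjusted over the list alone (camera adjusted p = 0.0536). The camera adjusted p of this pair was between 0.0442 and 0.0489 without day 3 replicate 1, day 3 replicate 2 or day 7 replicate 3.

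Members of the coelichelin, coelibactin and Zur lists were higher on day 3, the coelibactin and zinc genes unevenly between replicates. For coelichelin, a peptide siderophore, all 11 members rose, with the same numbers adjusted over the list alone, at 7.71 ± 0.05 and 9.76 ± 0.03 (camera adjusted p = 3.6e-05, adjusted p = 0.351 with an estimated correlation). SCO0489 rose from 307 ± 73.1 to 2547 ± 253. For coelibactin, 11 of 11 members rose, 7 of them from values listed at 0 in all day 1 libraries (the same numbers adjusted over the list alone; camera adjusted p = 0.063). The day 3 level was 2.74 in replicate 1, 6.66 in replicate 2 and 1.03 in replicate 3. The levels in replicates 1 and 3 are low, and the lower quartile of all values also went from 4 on day 1 to 7.33 ± 1.15 on day 3. Outside replicate 2 the coelibactin rises therefore cannot be told apart from the general lift of low values. Genes under the zinc regulator Zur had 9 of 11 members higher (the same numbers adjusted over the list alone; camera adjusted p = 0.0726), at 4.47 ± 0.15 on day 1 and 6.99, 9.63 and 4.96 in the 3 day 3 replicates. Without day 3 replicate 2 the mean change was 1.71 for coelibactin and 1.50 for the zinc list. Without day 3 replicate 3 the camera adjusted p was 0.00428 and 0.00362, and without day 3 replicate 1 it was 0.0425 for coelibactin.

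In 7 further lists most members were higher on day 3 than on day 1. SapB (ram), a surface peptide of aerial growth, had 5 of 5 members higher (the same numbers adjusted over the list alone), at 1.21 ± 0.03 and 6.83 ± 0.92 (camera adjusted p = 0.00165, adjusted p = 0.39 with an estimated correlation). For hopanoid synthesis, 10 of 13 members rose and 3 did not pass, with 11 higher adjusted over the list alone, at 6.54 ± 0.02 and 7.77 ± 0.05 (camera adjusted p = 8.0e-04, adjusted p = 0.363 with an estimated correlation). For the terpenes geosmin, 2-methylisoborneol and albaflavenone, all 5 members rose, with the same numbers adjusted over the list alone (camera adjusted p = 0.0103, adjusted p = 0.363 with an estimated correlation). The cytochrome P450 SCO5223 rose from 26 ± 3 to 186 ± 14.2. The lanthipeptide cluster around SCO0267 had 4 of 4 members higher (the same numbers adjusted over the list alone; camera adjusted p = 0.0444, adjusted p = 0.417 with an estimated correlation; 0.0551 without day 1 replicate 3). Camera did not call the other 3 lists. In the lanthipeptide cluster around SCO6927, 5 of 6 members rose and 1 did not pass, with the same numbers adjusted over the list alone, at 3.07 ± 0.13 and 4.27 ± 0.36 (camera adjusted p = 0.184). For the grey spore pigment, 7 of 8 members rose and 1 did not pass, with the same numbers adjusted over the list alone, at 1.64 ± 0.22 and 2.86 ± 0.25 (camera adjusted p = 0.172). These levels are low, and the lower quartile of all values also went from 4 on day 1 to 7.33 ± 1.15 on day 3. Among phosphate starvation genes, 8 of 13 members rose, 1 fell and 4 did not pass, with the same numbers adjusted over the list alone (camera adjusted p = 0.338). The hydrolase SCO1968 rose from 2.67 ± 1.15 to 230.3 ± 78.7.

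Most genes of the lists for growth and aerobic respiration were lower on day 3, but the NADH dehydrogenase genes were higher. Of the ribosomal protein genes, 31 of 31 fell (the same numbers adjusted over the list alone), and the level went from 13.24 ± 0.07 to 10.84 ± 0.16 (camera adjusted p = 8.2e-12, adjusted p = 0.398 with an estimated correlation). For ATP synthase, 8 of 8 fell (the same numbers adjusted over the list alone), from 11.84 ± 0.10 to 8.99 ± 0.13 (camera adjusted p = 7.1e-05, adjusted p = 0.39 with an estimated correlation), and for the cytochrome bc1-aa3 branch 6 of 6 fell (the same numbers adjusted over the list alone), from 12.13 ± 0.01 to 9.02 ± 0.20 (camera adjusted p = 1.9e-04, adjusted p = 0.39 with an estimated correlation). Of the NADH dehydrogenase genes, which feed the same chain, 14 of 14 rose (the same numbers adjusted over the list alone), from 4.20 ± 0.09 to 8.16 ± 0.42 (camera adjusted p = 4.4e-08, adjusted p = 0.39 with an estimated correlation). In the list of cytochrome bd oxidase and nitrate reductases, 4 of 14 members rose, 2 fell and 8 did not pass, with the same numbers adjusted over the list alone (camera adjusted p = 0.263), with the nitrate reductase subunit beta NarH3 (SCO4948) rising from 6 ± 1 to 6144 ± 415 and the cytochrome oxidase subunit I SCO3945 falling from 6374 ± 237 to 1186 ± 177. All 11 genes of the TCA cycle fell (the same numbers adjusted over the list alone), from 11.34 ± 0.15 to 9.60 ± 0.15 (camera adjusted p = 3.0e-05, adjusted p = 0.39 with an estimated correlation). For glycolysis, 1 of 9 members rose and 8 fell, with the same numbers adjusted over the list alone (camera adjusted p = 0.0049, adjusted p = 0.455 with an estimated correlation). In DNA replication and cell division, 1 of 11 members rose, 8 fell and 2 did not pass, with the same numbers adjusted over the list alone (camera adjusted p = 0.00491, adjusted p = 0.455 with an estimated correlation), and FtsZ (SCO2082), which forms the division ring, went from 1144 ± 112 to 433 ± 53.5. Among heat-shock chaperones, 6 of 8 members fell and 2 did not pass, with the same numbers adjusted over the list alone (camera adjusted p = 0.00259, adjusted p = 0.264 with an estimated correlation). The co-chaperonin GroES (SCO4761) fell from 23789.7 ± 2554 to 2618 ± 306. These directions were the same under every scaling tried for these lists.

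Other lists moved in part or in both directions. The oxidative and thiol stress list had 6 members higher, 7 lower and 1 not called of 14 (the same numbers adjusted over the list alone; camera adjusted p = 0.169). The alkyl hydroperoxide reductase SCO5032 fell from 3283 ± 257 to 124 ± 33.2. Gas vesicle genes lie in 2 groups of neighbouring numbers, and the 10 that fell were SCO6499 to SCO6508 and the 8 that rose were SCO0649 to SCO0656 (9 higher and 10 lower adjusted over the list alone; camera adjusted p = 0.0409, adjusted p = 0.434 with an estimated correlation; 0.0656 after median-centring). For isorenieratene, 3 of 7 members fell and 4 did not pass, with the same numbers adjusted over the list alone (camera adjusted p = 0.254). In chitin and N-acetylglucosamine use, 2 of 10 members rose, 4 fell and 4 did not pass, with the same numbers adjusted over the list alone (camera adjusted p = 0.327). The PTS transmembrane protein SCO2907 fell from 84 ± 18.4 to 4 ± 0. For ectoine, 4 of 4 members fell (the same numbers adjusted over the list alone), from 8.39 ± 0.08 to 6.50 ± 0.25 (camera adjusted p = 0.00468, adjusted p = 0.388 with an estimated correlation). In the list of type III polyketide synthases for tetrahydroxynaphthalene and germicidin, 1 of 4 members rose and 3 did not pass, with the same numbers adjusted over the list alone (camera adjusted p = 0.594). The member that rose, the polyketide synthase SCO7221, went from 4.33 ± 0.577 to 93.3 ± 16.2. Of the pleiotropic antibiotic regulators, 7 rose, 4 fell and 5 did not pass (the same numbers adjusted over the list alone; camera adjusted p = 0.674), a mean change of 0.67 beside a median of -0.00193, with the regulator SCO5582 going from 34 ± 8.72 to 976.0 ± 144.3. The 8 largest falls over all genes lay outside these lists: the amino oxidase SCO1454 from 382 ± 26 to 5.33 ± 1.15, the flavohemoprotein SCO7428 from 1373 ± 43.6 to 24.3 ± 4.16, the adenosine deaminase SCO7268, the hydrolase SCO1455, SCO4782, the solute-binding protein SCO4286, the lipoprotein SCO1557 and SCO3897, with log2 changes between -5.93 and -4.91. The contrast called 5641 genes, 3186 higher and 2455 lower, a share of 56.5% higher against 42.1% after quantile normalisation.

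**Figure D3:**
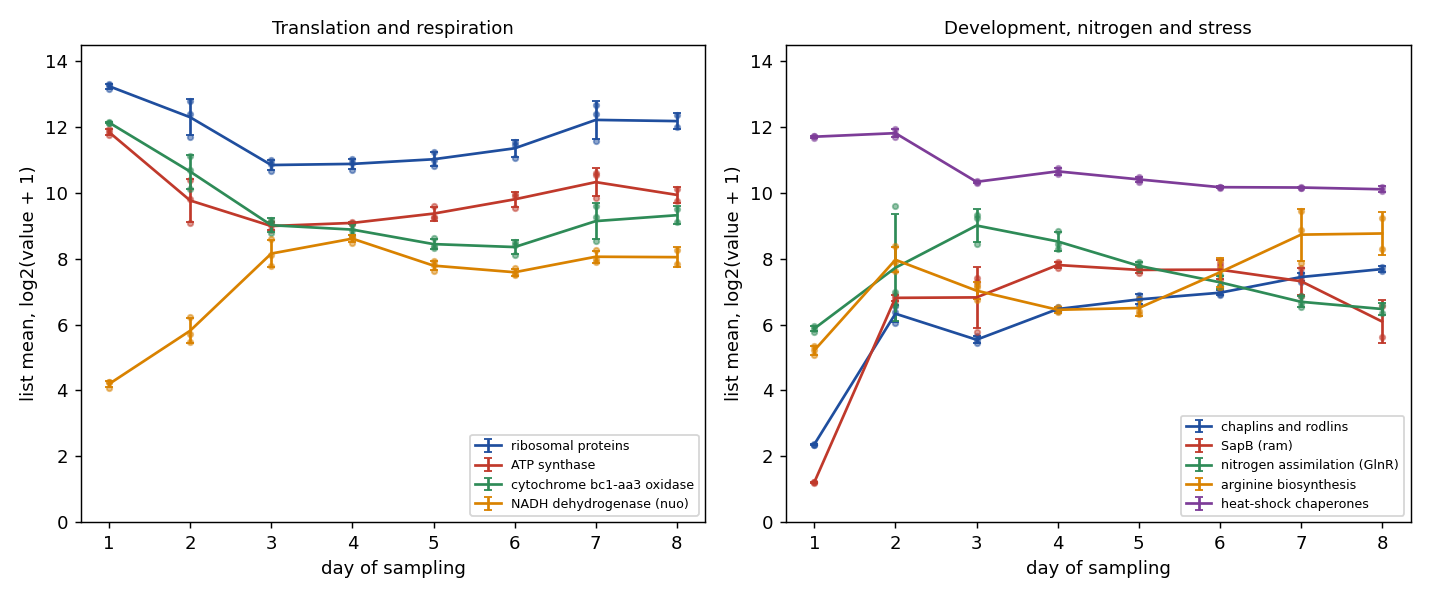
Level of gene lists for growth and respiration (left) and for development, nutrients and stress (right) by day, as the mean of log2(normalised expression + 1) over the members. Points are libraries, lines join day means and bars are SD. The NADH dehydrogenase list goes from 4.20 ± 0.09 on day 1 to 8.16 ± 0.42 on day 3, while the ATP synthase list goes from 11.84 ± 0.10 to 8.99 ± 0.13.

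Days 4 to 7 against day 1 gave counts of the same order. Among the 8 largest rises on day 5 were 6 actinorhodin genes (SCO5073, SCO5072, SCO5087, SCO5086, SCO5088 and SCO5074), the regulatory protein SCO4677 and SCO6682, a member of the SapB list, which went from 11.7 ± 2.31 to 14895 ± 1469. SCO5073, an oxidoreductase of the actinorhodin cluster, went from 1 ± 1 to 4113 ± 481. The 8 largest falls on day 5 included the neighbouring SCO5655, from 2777 ± 95.0 to 35.7 ± 2.08, and SCO5656, a transcriptional regulator, from 4566 ± 404 to 63.3 ± 9.02. The transketolase SCO6663 fell from 2914 ± 356 to 46.7 ± 3.51 and its neighbour in number, the transaldolase SCO6662, from 3152 ± 312 to 104 ± 22.8. SCO4286, SCO7428, SCO5032 and SCO1557 completed the 8, with log2 changes between -5.30 and -4.97. The contrasts called 5943 genes on day 4 (3482 higher, 2461 lower), 6014 on day 5 (3576 higher, 2438 lower), 6424 on day 6 (4053 higher, 2371 lower) and 6074 on day 7 (3646 higher, 2428 lower). The share of higher genes was 58.6%, 59.5%, 63.1% and 60.0%. After quantile normalisation it was 40.7%, 41.4%, 42.0% and 41.3%, after median-centring it was 48.3% on day 5, 50.1% on day 6 and 49.8% on day 7, after background subtraction 52.2% on day 6, and with equal protein-gene sums 69.8% on day 5.

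Day 8 against day 1 compares the last with the first sampling. Genes for the surface of aerial hyphae were higher, and regulators of development went both ways. The cultures were liquid, so the names of these lists do not show that aerial hyphae formed. Of the chaplins and rodlins, 10 of 10 rose (the same numbers adjusted over the list alone), from 2.36 ± 0.03 to 7.69 ± 0.10 (camera adjusted p = 1.7e-05, adjusted p = 0.146 with an estimated correlation). SCO1800 reached 17708 ± 2030.1 from 23.7 ± 8.08. In the list of bld and whi regulators of development, 9 of 16 members rose, 4 fell and 3 did not pass, with the same numbers adjusted over the list alone (camera adjusted p = 0.274). Over all genes, 3397 of 7831 were called higher and 2363 lower. The 4 members that fell are counted but not named. The largest rises in the list were the RNA polymerase sigma factor SCO3323, from 7.33 ± 2.31 to 1247 ± 2.83, and the 2-component regulator SCO4768, from 18.3 ± 3.21 to 1368 ± 54.4. The sporulation transcription factor WhiH (SCO5819) rose from 6.33 ± 2.52 to 249 ± 7.07 and the sigma factor WhiG (SCO5621) from 5 ± 1 to 47 ± 1.41. In the deoxysugar cluster, 21 of 21 members were still higher than on day 1 (the same numbers adjusted over the list alone), at 9.33 ± 0.12 (camera adjusted p = 1.4e-15, adjusted p = 0.337 with an estimated correlation). The polyunsaturated fatty acid type cluster, listed at 0 in all day 1 libraries for its 6 members, stood at 2.68 ± 0.12 with 6 members higher (the same numbers adjusted over the list alone; camera adjusted p = 0.0824; 0.0493 after median-centring). Its 2 most changed members, SCO0125 and SCO0126, were at 8.5 ± 0.707 and 7 ± 0, below the day 8 lower quartile of 10. These rises therefore cannot be told apart from the general lift of low values after day 1.

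Of the 8 largest rises on day 8, SCO4677 and SCO2804 were listed at 0 in all day 1 libraries and stood at 2322 ± 435 and 1054 ± 188. SCO1329, SCO1628, SCO1330, SCO3288, the lipoprotein SCO0930 and SCO1800 completed them, with log2 changes between 9.32 and 9.66. The transcriptional regulator SCO5656 had the largest fall, from 4566 ± 404 to 31.5 ± 9.19, followed by SCO5655, the dehydrogenase SCO4945, SCO7428, SCO1454, SCO4286, the gas vesicle synthesis protein SCO6499 and the cytochrome P450-family protein SCO7417, with a log2 change of -5.10 for the last. Desferrioxamine, a hydroxamate siderophore, had 4 of 4 members lower (the same numbers adjusted over the list alone), from 9.29 ± 0.29 to 6.29 ± 0.63 (camera adjusted p = 0.00265, adjusted p = 0.39 with an estimated correlation). All 9 glycolysis genes fell (the same numbers adjusted over the list alone; camera adjusted p = 3.0e-05, adjusted p = 0.39 with an estimated correlation), among them the glyceraldehyde-3-phosphate dehydrogenase SCO1947 from 9283 ± 1451 to 1102 ± 14.1. For RNA polymerase and elongation factors, 1 of 7 members rose, 3 fell and 3 did not pass, with the same numbers adjusted over the list alone (camera adjusted p = 0.241). The elongation factor Tu SCO4662 fell from 27513 ± 1262 to 6628 ± 462. The superoxide dismutase SCO2633 fell from 16343 ± 1059 to 1638 ± 216. The contrast called 5760 genes, 3397 higher and 2363 lower, a share of 59.0% higher against 41.5% after quantile normalisation.

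From day 2 to day 3 the antibiotic clusters parted. All 22 actinorhodin genes rose further (the same numbers adjusted over the list alone; camera adjusted p = 9.0e-21, adjusted p = 0.213 with an estimated correlation) and SCO5085, the cluster activator, went from 1649.7 ± 349.6 to 10524 ± 1685. For the calcium-dependent antibiotic, 36 of 40 members fell and 4 did not pass, with 37 lower adjusted over the list alone (camera adjusted p = 2.7e-07, adjusted p = 0.556 with an estimated correlation), at 7.75 ± 0.71 and 6.53 ± 0.34. All 10 genes of the cluster around SCO6429 fell (the same numbers adjusted over the list alone; camera adjusted p = 9.2e-05, adjusted p = 0.553 with an estimated correlation). For maltose uptake, all 5 members fell, with the same numbers adjusted over the list alone (camera adjusted p = 5.0e-05, adjusted p = 0.254 with an estimated correlation). The maltose-binding protein SCO2231 fell from 3787 ± 1633 to 469.7 ± 66.2. All 8 heat-shock chaperone genes fell (the same numbers adjusted over the list alone; camera adjusted p = 9.4e-07, adjusted p = 0.0841 with an estimated correlation). All 31 ribosomal protein genes fell (the same numbers adjusted over the list alone; camera adjusted p = 2.0e-11, adjusted p = 0.553 with an estimated correlation), while all 14 NADH dehydrogenase genes rose (the same numbers adjusted over the list alone; camera adjusted p = 1.6e-14, adjusted p = 0.254 with an estimated correlation). The largest rise was that of the 4-hydroxyphenylpyruvate dioxygenase SCO2927, a step of tyrosine breakdown, from 192.3 ± 80.4 to 11848 ± 3312, followed by the membrane transport protein SCO1710 and the 2-amino-3-ketobutyrate coenzyme A ligase SCO6800. The flavohemoprotein SCO7428 fell from 1503 ± 525 to 24.3 ± 4.16, followed by SCO6663 and SCO7427. The contrast called 3277 genes, 1528 higher and 1749 lower (46.6% higher, and 61.4% with equal protein-gene sums).

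From day 3 to day 4 several clusters fell back. For actinorhodin, 2 of 22 members rose, 15 fell and 5 did not pass, with 3 higher and 17 lower adjusted over the list alone (camera adjusted p = 3.3e-06, adjusted p = 0.52 with an estimated correlation), with SCO5087 going from 8385 ± 1921 to 2838 ± 365. For coelimycin, 16 of 20 members fell and 4 did not pass, with 18 lower adjusted over the list alone (camera adjusted p = 5.1e-12, adjusted p = 0.23 with an estimated correlation). For undecylprodigiosin, 14 of 22 members fell and 8 did not pass, with 19 lower adjusted over the list alone (camera adjusted p = 9.1e-10, adjusted p = 0.428 with an estimated correlation), a mean change of -1.32 that was -0.78 without day 3 replicate 3. All 4 desferrioxamine genes fell (the same numbers adjusted over the list alone; camera adjusted p = 9.7e-05, adjusted p = 0.346 with an estimated correlation). The tyrosine breakdown genes SCO2927 and homogentisate 1,2-dioxygenase (SCO1715) fell, from 11848 ± 3312 to 1362 ± 39.5 and from 644 ± 264 to 98.7 ± 4.73, as did SCO6800. SCO1105 rose from 21.3 ± 5.77 to 479.7 ± 164, the fatty acid CoA ligase SCO1330 from 10 ± 1 to 242 ± 182 and its neighbour SCO1329 from 6.67 ± 3.06 to 137 ± 114. Among chaplins and rodlins, 5 of 10 members rose and 5 did not pass, with 7 higher adjusted over the list alone (camera adjusted p = 5.2e-04, adjusted p = 0.197 with an estimated correlation). The small membrane protein SCO1675 rose from 677 ± 55.1 to 3666 ± 1392. The contrast called 1649 genes, 913 higher and 736 lower (55.4% higher, and 40.7% after median-centring). Without day 4 replicate 2 the number of higher genes was 608.

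Fewer genes were called between days 4 and 5 than between days 3 and 4. The phosphoenolpyruvate carboxykinase SCO4979, a gluconeogenic enzyme, rose from 57.7 ± 5.13 to 455 ± 134, and in its list of glyoxylate and gluconeogenesis genes 1 of 3 members rose and 2 did not pass, with 2 higher adjusted over the list alone (camera adjusted p = 2.1e-04, adjusted p = 0.197 with an estimated correlation). The transport protein SCO1822 and its neighbour SCO1823 rose from 8.33 ± 0.577 to 80.7 ± 3.79 and from 6 ± 3 to 57.3 ± 9.61. The glyceraldehyde 3-phosphate dehydrogenase SCO7511 fell from 3293 ± 73.4 to 520 ± 96.5, SCO1105 from 479.7 ± 164 to 127 ± 17.7 and the lipoprotein SCO7546 from 11.3 ± 1.15 to 2 ± 1. The contrast called 346 genes, 145 higher and 201 lower (41.9% higher, and 75.5% with equal protein-gene sums). The count was 219 (95 higher and 124 lower) without day 4 replicate 1, 182 (83 higher and 99 lower) without day 4 replicate 3, 175 (84 higher and 91 lower) without day 5 replicate 1 and 175 (80 higher and 95 lower) without day 5 replicate 3. The number of lower genes was 118 without day 4 replicate 2.

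Between days 5 and 6, SCO6164, SCO6165 and SCO6166, neighbours in number that the table lists as hypothetical proteins, rose from 8.33 ± 2.31 to 455 ± 43.5, from 7 ± 1.73 to 250 ± 32.0 and from 7 ± 2 to 320 ± 70.6. For isorenieratene, 5 of 7 members rose and 2 did not pass, with 7 higher adjusted over the list alone (camera adjusted p = 2.4e-05, adjusted p = 0.254 with an estimated correlation), at 3.60 ± 0.18 and 4.85 ± 0.04. All 11 coelichelin genes fell (the same numbers adjusted over the list alone; camera adjusted p = 1.2e-13, adjusted p = 0.116 with an estimated correlation). The alcohol dehydrogenase SCO0259 and its neighbours SCO0257 and SCO0258 fell, SCO0259 from 167 ± 30.4 to 24.7 ± 5.03. The contrast called 1109 genes, 829 higher and 280 lower (74.8% higher, against 45.0% after median-centring, 53.0% after quantile normalisation and 58.4% after background subtraction). The count was 349 (257 higher and 92 lower) without day 5 replicate 1, 460 (347 higher and 113 lower) without day 5 replicate 3, 675 (504 higher and 171 lower) without day 6 replicate 1 and 364 (267 higher and 97 lower) without day 6 replicate 2. The headers of the 2 sets of columns disagree on which library is day 5 replicate 2 and which is day 6 replicate 2. With these 2 libraries exchanged, as the RPKM headers have them, limma called 0 genes and 101 had an unadjusted p under 0.05, so under that exchange none of the gene calls in this paragraph held, list members included. The levels of 2 lists named above go with the expression headers used here. Coelichelin was at 8.93 in day 5 replicate 2 (8.93 and 8.95 in the other day 5 libraries) and at 8.21 in day 6 replicate 2 (8.13 and 8.25). Isorenieratene was at 3.76 (3.41 and 3.62) and 4.89 (4.81 and 4.84). With both libraries left out the count was 376.

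From day 6 to day 7 lists for growth and respiration were higher again, less so in day 7 replicate 2. Of the ribosomal protein genes, 29 of 31 rose (31 higher adjusted over the list alone), from 11.35 ± 0.25 to 12.21 ± 0.57 (camera adjusted p = 2.0e-17, adjusted p = 0.428 with an estimated correlation). All 6 genes of the cytochrome bc1-aa3 branch rose (the same numbers adjusted over the list alone; camera adjusted p = 7.8e-05, adjusted p = 0.458 with an estimated correlation), and of the TCA cycle genes 6 of 11 did (10 higher adjusted over the list alone; camera adjusted p = 4.1e-07, adjusted p = 0.422 with an estimated correlation). All 7 arginine biosynthesis genes rose (the same numbers adjusted over the list alone), from 7.59 ± 0.43 to 8.73 ± 0.79 (camera adjusted p = 4.5e-06, adjusted p = 0.398 with an estimated correlation). In day 7 replicate 2 the ribosomal protein level was 11.58, against 12.39 and 12.68 in the other day 7 libraries and 11.07 to 11.53 on day 6. In that library the TCA cycle level of 8.95 and the arginine level of 7.88 lay within the day 6 values (8.59 to 8.98 and 7.11 to 7.96). The low end on day 6 was day 6 replicate 2 in each case, at 11.07 for ribosomal proteins, 8.59 and 7.11. Against that library of the same number, all of these levels were higher in day 7 replicate 2. The labels do not say what a number shares between days. For coelichelin, all 11 members fell, with the same numbers adjusted over the list alone (camera adjusted p = 8.0e-09, adjusted p = 0.213 with an estimated correlation), and for hopanoids 10 of 13 members fell and 3 did not pass, with 1 higher and 10 lower adjusted over the list alone (camera adjusted p = 2.4e-05, adjusted p = 0.254 with an estimated correlation). The glycosyl hydrolase SCO6572 rose from 137 ± 159.7 to 827 ± 191, SCO6580 from 101 ± 106 to 673 ± 132 and SCO6579 from 28 ± 27.1 to 148 ± 37.1. The largest falls were those of the membrane transport protein SCO1010 from 80.3 ± 29.0 to 16.7 ± 8.02, SCO3935 from 10.3 ± 5.13 to 1.33 ± 0.577 and SCO5615 from 6 ± 4.36 to 0.667 ± 1.15. The contrast called 1296 genes, 485 higher and 811 lower (37.4% higher, against 66.3% after median-centring, 48.1% after quantile normalisation, 52.5% after background subtraction and 7.44% with equal protein-gene sums). The count was 376 (114 higher and 262 lower) without day 6 replicate 2, 493 (132 higher and 361 lower) without day 7 replicate 1 and 475 (167 higher and 308 lower) without day 7 replicate 3. The number of higher genes was 767 without day 7 replicate 2. The adjusted p of SCO3935 and SCO5615 was 0.0691 and 0.121 without day 6 replicate 2 and that of SCO5615 0.084 without day 7 replicate 1. With day 5 and day 6 replicate 2 exchanged the count was 709 and the adjusted p of SCO1010 was 0.0746.

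The fewest genes were called between days 7 and 8, a contrast with 2 libraries on day 8. With day 5 and day 6 replicate 2 exchanged the order turned, with 65 genes for this contrast and 0 by limma, 101 at an unadjusted p under 0.05, between days 5 and 6. The metallopeptidase SCO6736 rose from 68.3 ± 22.3 to 1112 ± 765, the regulatory protein SCO2213 from 70.7 ± 63.5 to 645 ± 492 and SCO5771 from 41 ± 46.0 to 282 ± 198. SCO6682 of the SapB list fell from 16894 ± 5044 to 2799 ± 2611, and 2 of the 5 members of the list fell (3 lower adjusted over the list alone; camera adjusted p = 2.5e-04, adjusted p = 0.398 with an estimated correlation). The DNA-binding protein SCO7828 and SCO0019 were at 3.33 ± 1.53 and 3.33 ± 1.53 on day 7 and listed at 0 in both day 8 libraries. The contrast called 95 genes, 85 higher and 10 lower (89.5% higher, and 77.7% after background subtraction). A fit on only the libraries of days 7 and 8 called 0 genes by limma, with 542 at an unadjusted p under 0.05 and a lowest adjusted p of 0.343, so in that fit none of the gene calls in this paragraph held. In the fit on all days the count was 20 (20 higher and 0 lower) without day 7 replicate 1, 47 (40 higher and 7 lower) without day 7 replicate 2 and 18 (18 higher and 0 lower) without day 8 replicate 3. The number of lower genes was 29 without day 7 replicate 3. Where limma called 0 lower genes, 243 without day 7 replicate 1 and 256 without day 8 replicate 3 were lower at an unadjusted p under 0.05. Without day 8 replicate 3 the adjusted p was 0.148 for SCO2213, 0.269 for SCO5771 and 0.457 for SCO6682, whose log2 change moved from -2.96 to -1.81, and the change of the SapB list moved from -1.22 to -0.76. Without day 7 replicate 1 the adjusted p was 0.0682 for SCO5771 and 0.0759 for SCO6682, without day 7 replicate 2 it was 0.0605 for SCO6682. For SCO7828 and SCO0019 it was between 0.0501 and 0.282 without any 1 of the libraries of days 7 and 8, of day 1, day 3 replicates 1 and 3, day 5 replicate 3 or day 6 replicate 1.

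**Figure D4:**
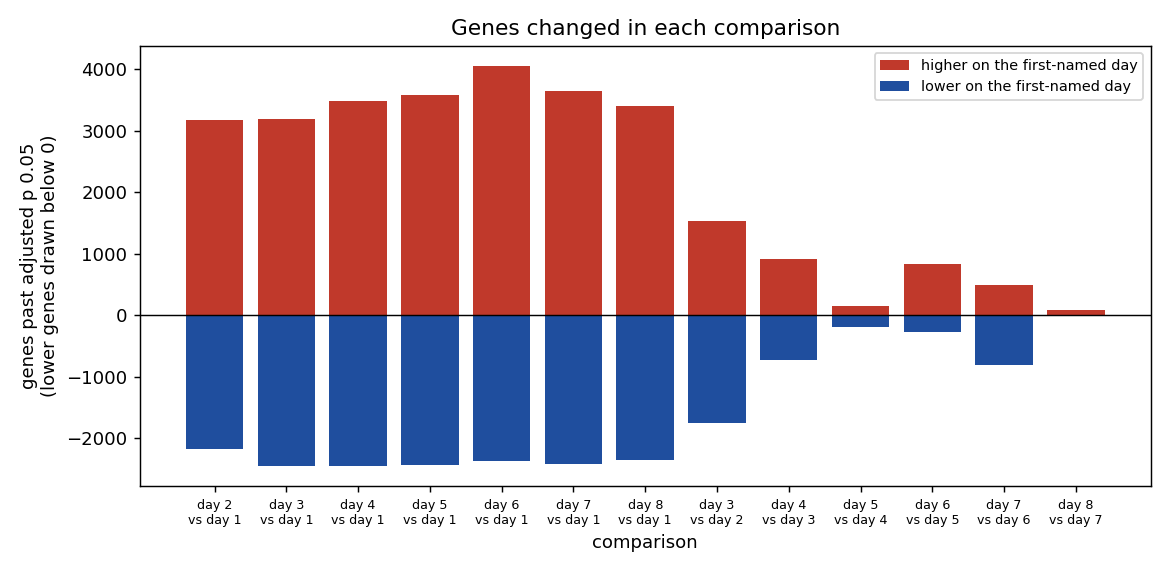
Number of genes called higher (bars above 0) and lower (bars drawn below 0) by limma at an adjusted p below 0.05, against day 1 and between consecutive days. The calls against day 1 number 5345 to 6424, while consecutive days differ by 3277 genes from day 2 to day 3 and 95 from day 7 to day 8.

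Over the 42 lists and 13 contrasts, camera with its preset correlation called 238 of 546 list tests, 145 of 294 against day 1 and 93 of 252 between consecutive days. With an estimated correlation camera called 0, the lowest adjusted p was 0.0841 and 69 had an unadjusted p under 0.05, while fry, which tests whether members move one way on balance, called 269 and 83. Random regroupings of the libraries gave up to 232 camera calls with the preset correlation. They mix libraries of different days and do not measure false calls. Since the estimated correlation left 0 calls, the preset p-values carry little weight. The statements on lists above rest on levels, replicate spread and member counts. Members were measured in the same libraries and can vary together, so they are not independent supports. Where nearly all members pass over all genes, adjusting over the list alone is no further check. Member counts are best read beside all genes: on day 2 against day 1, 3173 of 7831 were called higher and 2172 lower.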

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

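All tests in this part were chosen after the results were seen. The RPKM column headed day 5 replicate 2 correlated across genes with the expression column of the same header at 0.965, and the one headed day 6 replicate 2 at 0.968, on values that the comparisons do not use. Each was closer to the expression column of the other, at 0.995 and 0.996. These are correlations across genes, which are not independent replicates.

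The values argue against an exchange of the expression headers. Over 377 genes called between the other day 5 and day 6 libraries (376 of them are called when the filter is applied again to the 21 libraries left, which drops 8 further genes), a place of 0 stands for the other day 5 libraries and 1 for the other day 6 libraries. The expression column headed day 5 replicate 2 had a median place of 0.348 and the one headed day 6 replicate 2 a median place of 1.19, where an exchange would put the first near 1 and the second near 0. In 18 of 42 gene lists the other libraries of days 5 and 6 lay further apart than the libraries within either day. In 10 of these lists both columns were nearer the day of their header, in 8 only 1 of the columns was, and in 0 were both nearer the other day. An exchange of the RPKM headers goes with these values and may be the source of the disagreement. No biological explanation was tested, since a header is not a property of the culture.

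Fewer genes were listed at 0 after day 1, at 918 ± 24.2 per library on day 1 and 28 ± 15.1 on day 6. Scaling of whole libraries multiplies both quartiles alike. The lower quartile as a percentage of the upper moved by 9.17 points between days 1 and 6, from 3.42 ± 0.0511 to 12.6 ± 1.70. This argues against scaling as the cause. The upper quartile was nearly the same in all libraries, so the percentage restates the lift of the lower quartile and is no separate evidence. Reads spread evenly over the genome, such as from residual DNA, could also lift low genes. Among the 1958 genes with the lowest means, 691 of 1514 rises on day 6 (45.6%) stayed past the threshold after the 5th percentile was subtracted. That share lies between the bounds set for and against such a background, so it cannot be told apart from a biological widening of transcription.

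The NADH dehydrogenase genes rose from day 1 to day 3 while ATP synthase and cytochrome bc1-aa3 genes fell. A single scale factor per library cannot raise 1 list and lower another, so the pattern itself argues against it as the whole cause. The log2 difference within libraries between the NADH dehydrogenase and ATP synthase levels changed by 6.81, which restates the pattern and is no separate evidence. An evenly spread background adds the same amount to all genes. The 5th percentile over all genes was 0 in the day 1 libraries and 1 to 2 in those of day 3. Subtracting so little could hardly change the NADH dehydrogenase level, which still rose by 3.95. A background of that size is too small to be the cause of that rise. The subtraction adds no evidence beyond these sizes. A change in the use of the respiratory chain with culture age may remain as a hypothesis, found in these data and not tested.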

How the results depend on the processing

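The background and protein-sum alternatives, and exchanging or leaving out day 5 and day 6 replicate 2, were chosen after the data were seen. The others were chosen before the data were examined. The count over all days was within 1.5 times of 7139 under all alternatives run. The total counts against day 1 were too, except that with an added 2-fold threshold day 2 gave 3409 genes. The split by direction moved more. From day 2 to day 8, quantile normalisation gave 1734, 2108, 2159, 2228, 2402, 2211 and 2088 higher genes, against 3173, 3186, 3482, 3576, 4053, 3646 and 3397. Without the 25% of genes with the lowest means, 2536, 2390 and 2259 were higher on days 6 to 8. With the 2-fold threshold 1088, 1554, 1623, 1618 and 1587 were lower on days 2 to 5 and 7. The count model was not run because the values are not counts.

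Counts between consecutive days moved more. With the 2-fold threshold they were 1466 for days 2 and 3, 628 for days 3 and 4, 125 for days 4 and 5, 453 for days 5 and 6, 402 for days 6 and 7 and 60 for days 7 and 8, as that threshold requires. Library weights gave 2959, 1529, 2510, 2591 and 189 from days 3 and 4 to days 7 and 8. Days 7 and 8 gave 62 genes without the trend. Fits on only the compared libraries gave 646 for days 4 and 5, 674 for days 6 and 7 and 0 by limma for days 7 and 8, where 542 had an unadjusted p under 0.05. Equal protein sums gave 2230 for days 6 and 7. Exchanging day 5 and day 6 replicate 2 gave 0 for days 5 and 6 by limma, with 101 at an unadjusted p under 0.05, and 709 for days 6 and 7, and leaving both out gave 376 and 366. Apart from the 2-fold threshold, which can only lower a count, the causes of these moves were not tested.

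Leaving out 1 library in turn gave 175 to 391 genes for days 4 and 5, 349 to 1296 for days 5 and 6, 376 to 1885 for days 6 and 7, and 18 to 128 for days 7 and 8. Days 3 and 4 ranged from 1130 to 1783 and days 2 and 3 from 2770 to 3397. Where a single library is left on day 8, it is assumed to vary like the other days.

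With the replicate block the count over all days was 7259, that for days 5 and 6 was 1530, for days 6 and 7 1786 and for days 7 and 8 117. Deviations from the day means had a median correlation of 0.0891 in 77 pairs of libraries with the same number, from -0.144 to 0.543, against -0.0302 in other pairs. Of the 77, 38 exceeded 0.1, and 17 of 23 libraries correlated best with their own number. This is a hint from the data that numbers share something across days, though not in every pair, and the labels do not state it.

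Camera called 238 list tests, 232 to 250 without 1 library, 0 with an estimated correlation, where 69 had an unadjusted p under 0.05, and fry called 352.

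Of 387 gene results, 5 changed sign or came to 0, and the cause was not tested. SCO6265 on day 8 against day 1 was -0.0600 after median-centring. After quantile normalisation SCO1429 on day 3 was -0.0460 and SCO4035 on day 8 was -0.21. SCO1207 on day 3 was 0.0224 with library weights, 0.0922 with equal protein sums, and between -0.18 and 0.0048 without 1 library, the highest without day 3 replicate 3. SCO0127 on day 3 came to 0 after background subtraction, without a change of sign.

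Of 135 list results, undecylprodigiosin on day 2 against day 1 was -0.0142 after median-centring, -0.28 after quantile normalisation, -0.0907 after background subtraction, and between -0.0505 and 0.35 without 1 library. Coelichelin on day 8 against day 1 was -0.32 after median-centring, -0.0124 after background subtraction, and between -0.0729 without day 8 replicate 3 and 0.0910 without day 8 replicate 2. After quantile normalisation isorenieratene on day 8 was -0.26, the grey spore pigment on day 8 -0.0177, the polyunsaturated fatty acid type on day 3 -0.21 and phosphate starvation on day 8 -0.0654. The cause was not tested.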

Other observations

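The tests over splits in this part were chosen after the results were seen, and the fits on both days alone were among the alternatives chosen earlier. Of 100 splits of the 23 libraries, the real one included, 1 gave as many F test calls as the 7139 of the real days. The highest of the other splits called 0, which argues against there being no difference at all between the days. Random splits put the differences between days into the spread, so the comparison does not bear on the size of the count. For list tests 1 of 100 splits reached the real count of 238, and the highest other was 232. These splits also mix days, so 232 does not measure false calls. The number of list calls alone says little about which lists differ between days.

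For each pair of days with 3 libraries each there are 10 splits, too few for a share under 0.05, and the real split alone, 1 of 10, gave the largest count in each. In fits on both days alone the real counts against day 1 were 5136 on day 2, 5495 on day 3, 5811 on day 4, 6035 on day 5, 6402 on day 6 and 5854 on day 7. Between consecutive days they were 2905 for days 2 and 3, 1686 for days 3 and 4, 646 for days 4 and 5, 1451 for days 5 and 6 and 674 for days 6 and 7. The highest of the other splits was 0 in every pair.

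Stable RNA genes covered a wide range of values. SCOs02 had a mean of 206084 ± 11513.1 on day 1 and 1470543 ± 122180 on day 5. The 23S ribosomal RNA gene SCOr02 went from 1817 ± 819 on day 1 to 264232 ± 33019 on day 6, and the 16S gene SCOr03 from 531 ± 314 to 11881 ± 734. The 5S gene SCOr01 was listed at 0 in all day 1 libraries and at 4 ± 1 on day 6. Another 23S copy, SCOr05, had nearly the same value as SCOr02 on day 6, at 264088 ± 33004. Ribosomal RNA was removed before sequencing, so the rRNA values depend on how much was left. They do not give its amount in the cells.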
